A study of Mus musculus with 12 samples.

How the data were processed

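The series measured gene expression in mouse embryonic stem (ES) cells that carry a tetracycline-inducible Neurog1 transgene. Neurog1 encodes a proneural basic helix-loop-helix transcription factor, and doxycycline switches the transgene on. Per the labels' protocols, the cells were of 129P2/OlaHsd origin (E14, Ainv15) and were kept in serum-containing medium with leukaemia inhibitory factor, puromycin and G418. Doxycycline was given at 1 ug/ml for 24, 48 or 72 h, per the labels' protocols, and the control cells were uninduced cells of the maintenance culture (0 h). Each of the 4 groups held 3 arrays that the labels call biological replicates, giving 12 Affymetrix arrays. Total RNA was extracted with Trizol and made into biotinylated cRNA, per the labels' protocols. Uninduced cells were sampled at 0 h alone, so the transgene, doxycycline itself and time in culture cannot be told apart by any comparison with them.

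The deposited values were intensity on a linear scale, 1 signal per probe set and array, made by the authors with MAS5, per the submitters' processing notes. The version, scaling target and settings of MAS5 are not given in the sources used here. Computed from the deposited values, the 2% trimmed mean of the signals was 150 on each of the 12 arrays. The table held 45101 probe sets, of which 64 were Affymetrix controls. No pair of arrays held identical values. The number of arrays limits the precision of every comparison.

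Probe sets were named through the platform annotation, and symbols were checked through Entrez identifiers against the NCBI gene table of assembly GRCm38.p6. In that annotation 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. By Entrez identifier 34754 of the 34945 were matched, and 0 symbols changed. No genome build is named for the arrays in the sources used here, so no coordinates are given. Probe sets without exactly 1 symbol entered no gene comparison.

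The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, apart from those said to be chosen afterwards. Signals were transformed as log2(signal + 16). Fold changes are therefore on the log2(signal + 16) scale, which understates the change of dim genes. The authors' scaling between arrays was kept. Of several probe sets of a gene, the one with the highest mean over all 12 arrays was used. A gene was tested where that probe set exceeded its array's median signal (percentile 50) on at least 3 arrays of any group, which left 12629 of 18193 genes. One linear model with 4 group terms was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend). Its 5 contrasts were each induced time against uninduced cells, 48 h against 24 h, and 72 h against 48 h. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. A second count took called genes with an absolute log2 difference of 1 or more. Differences are given as log2 difference ± standard error (SE) from limma, with n = 3 arrays per group.

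The 32 gene lists were drawn from general knowledge of these cells and overlap in part. They covered naive pluripotency, primed and formative pluripotency, the proneural cascade, the Notch pathway, sensory neurons and placodes, pan-neuronal genes, synapse, axon guidance, neural progenitors and glia. Markers of other cells were mesendoderm, endoderm, mesoderm and muscle, trophoblast, germline and 2-cell-like cells, fibroblasts and feeders, and neural crest. The others were epithelial adhesion, factors of the epithelial-mesenchymal transition, S phase, G2 and M phase, cell cycle exit, BMP and Id genes, the Wnt pathway, FGF and MAPK signalling, Hox genes, p53 targets, hypoxia and glycolysis, cholesterol synthesis, ribosomal proteins, the ATF4 stress response (a known cellular response to doxycycline), and immediate early and heat shock genes (signs of handling stress). Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, and adjusted by Benjamini-Hochberg over the 160 tests of 32 lists in 5 comparisons. The same test with an estimated correlation, and fry, were alternatives. Of the 160 tests, 89 passed with the preset correlation and 83 with fry. With an estimated correlation 1 passed, sensory neurons and placodes for 72 h against 48 h.

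Genes are named by rule. These are Neurog1 in every comparison, the 12 largest rises and 12 largest falls at each time against uninduced cells, and the 5 largest of each between consecutive times. Such genes had to be called, with all 3 arrays of one group on the same side of all 3 of the other. Symbols of unnamed transcripts (ending in Rik, starting with Gm, LOC, BC, AI, AW or AA plus digits, or ESTs) were left out of naming. In each list the 2 largest rises and 2 largest falls among called members could be named. Pou5f1, Nanog, Sox2, Tubb3, Dll1, Hes5, Neurod1, Neurod4, Id1, Cdkn1a and Cdkn1c could be named whether or not they passed. Genes named outside this rule are said to be so. Of 235 genes named by the rule, 114 had further probe sets above the filter. A further probe set moved the opposite way in 8 of 445 pairs of gene and comparison, which involved Dcc, Slc1a2, Tigar, Pfkp, Hsd17b7 and Neurog1.

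Comparisons that share the 3 uninduced arrays were set beside 100 simulated draws of unchanged groups against the same arrays, and beside the overlap of independent lists (n1 x n2 / N). The scripts were tested on simulated data of 12629 genes with 200 changed genes per comparison. Over the 5 simulated comparisons, 84.2% to 93.2% of genes changed by 2 on the log2 scale were recovered. At a change of 1 the range was 7.8% to 29.6%, and at 0.5 it was 0% to 1.6%. False calls numbered 3 to 6 per comparison. The simulated comparisons called 56 to 90 genes, whereas the real comparisons with uninduced cells called 1279 to 5213. The adjusted threshold is looser where more genes change, so these recovery rates do not give the sensitivity of those comparisons.

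Alternatives were pseudocounts of 1 and 64, quantile normalization, centring each array on its median, no filter and a filter at percentile 75, the mean of all probe sets of a gene, each probe set by itself, eBayes without trend or with robust estimation, a fit of the 6 arrays compared alone, a replicate block, and leaving out each of the 12 arrays in turn. Chosen after seeing the data were limma array weights, whose estimate stopped before its convergence tolerance was reached, leaving out the 4 arrays numbered 3 together, and the estimated correlation without induced 24 h replicate 1.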

Results

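Transcript levels were measured on 12 arrays of mouse ES cells carrying a doxycycline-inducible Neurog1 transgene, with 3 arrays each for uninduced cells (0 h) and for cells induced for 24, 48 and 72 h. The design addressed how expression changed after Neurog1 was switched on, with uninduced cells as the common control. Median signals ran from 19.5 to 32.8 over the 12 arrays. Values are log2 differences ± SE from limma with Benjamini-Hochberg adjustment, and each comparison set n = 3 arrays against n = 3. For each gene named among the largest changes, all 3 arrays of one group lay on one side of all 3 arrays of the other. Where a gene was near the floor in a group, the size of its difference and its place among the largest depend on the pseudocount.

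Neurog1 itself was near the floor in uninduced cells and high in every induced array. On the brighter of its 2 probe sets the signal was 4.53 to 18.7 in uninduced cells and 465 to 1152 in induced cells. The other probe set gave 1.68 to 7.385 in uninduced cells and 48.9 to 268 in induced cells. The log2 difference from uninduced cells was 5.06 ± 0.27 at 24 h, 5.29 ± 0.27 at 48 h and 4.58 ± 0.27 at 72 h. Between induced times Neurog1 did not pass, with 0.23 ± 0.27 for 48 h against 24 h (adjusted p = 0.581) and -0.71 ± 0.27 for 72 h against 48 h (adjusted p = 0.377). The 2 probe sets differed in sign in both of these comparisons. Which transcript a probe set reads, that of the transgene, the endogenous gene or both, is not given in the sources used here.

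**Figure D1:**
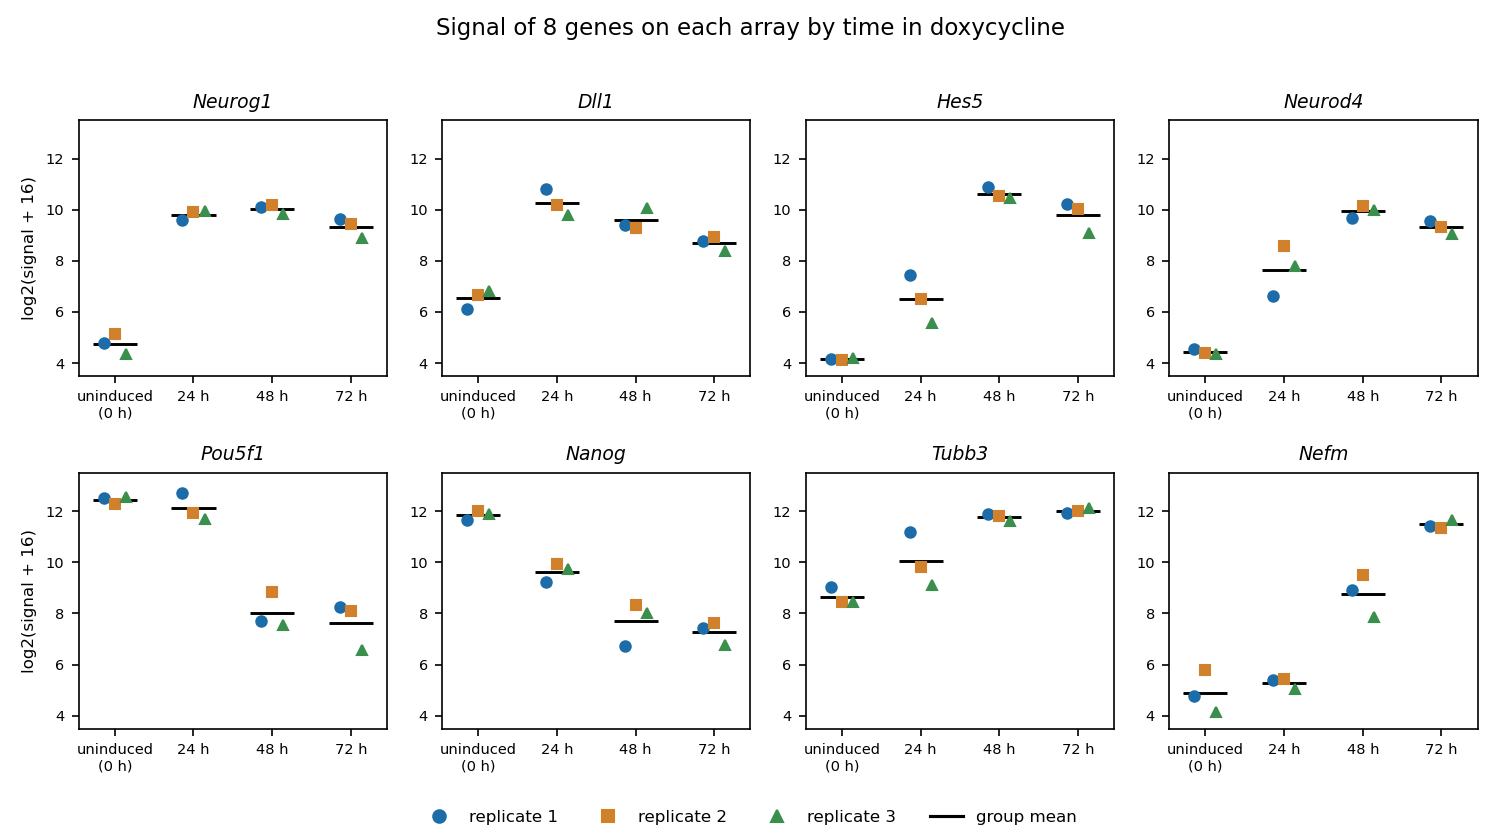
Signal of Neurog1, Dll1, Hes5, Neurod4, Pou5f1, Nanog, Tubb3 and Nefm on each of the 12 arrays, as log2(signal + 16) against time in doxycycline, with points for arrays by replicate number and bars for group means. Neurog1 was 4.36 to 5.12 on the uninduced arrays and 8.91 to 10.19 on the induced arrays, and Pou5f1 was 11.69 to 12.71 at 24 h and 7.55 to 8.83 at 48 h.

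One array stood apart from its group. Induced 24 h replicate 1 correlated at r = 0.804 and r = 0.826 with the other 24 h arrays across the tested genes, which are not independent replicates. All other pairs within a group reached at least r = 0.961, and the other 24 h arrays correlated with each other at r = 0.976. On this array 373 genes were at least 2-fold above and 1267 at least 2-fold below every other array. Its ratio of 3' to 5' signal was 6.81 for Pcx, against 1.22 to 2.8 on the other arrays. For Gapdh the ratio was 0.862, within the 0.658 to 0.864 of the others, and for Actb it was 1.42, within 1.34 to 1.54. The first principal component held 56.3% of the variance and the second 21.6%.

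**Figure D2:**
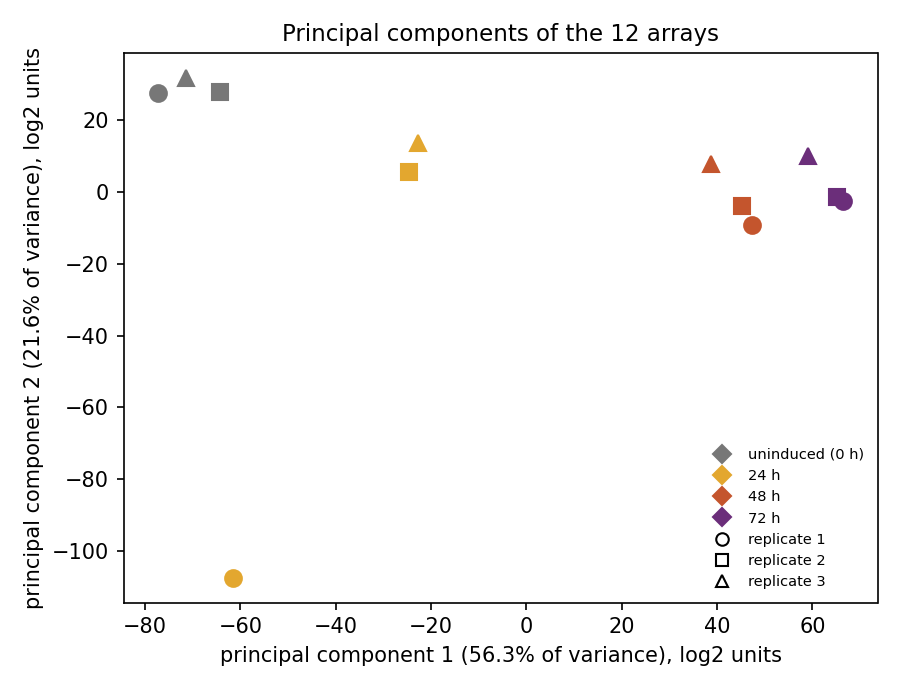
The 12 arrays on the first 2 principal components of the tested genes, in log2 units, coloured by group and shaped by replicate number. Induced 24 h replicate 1 lay at -107.39 on the second component, where the other 11 arrays lay between -9.08 and 31.74.

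After 24 h of induction, 18 of 33 tested proneural genes were higher than in uninduced cells and 17 of 38 naive pluripotency genes were lower (n = 3 against 3). The largest rises were Tff3, a secreted trefoil peptide (5.97 ± 0.47), Insm1, a zinc-finger factor of neuronal and endocrine progenitors (5.23 ± 0.48), and Spsb4 (5.12 ± 0.30). The helix-loop-helix factor Ebf2 rose by 5.02 ± 0.46, the T-box factor Tbx4 by 4.50 ± 0.35 and Doc2a, a calcium sensor of vesicle release, by 4.63 ± 0.31. Also among the 12 largest rises were Csn3 (4.87 ± 0.95), Gfra3, a receptor of the GDNF family (4.23 ± 0.54), Pkdcc (4.08 ± 0.32), Greb1l (4.07 ± 0.36) and the Notch ligand Dll3 (4.04 ± 0.46). The largest falls were Tdgf1, the Nodal co-receptor Cripto (-3.94 ± 0.71), Lgals3 (-3.77 ± 0.32), Spink1 (-3.74 ± 0.31) and the pluripotency factor Nr5a2 (-3.40 ± 0.45). Then came Xaf1 (-3.33 ± 0.25), the activin subunit gene Inhbb (-3.03 ± 0.28), Pramel6 (-3.02 ± 0.33) and Klf4 (-2.95 ± 0.29). The call of Pramel6 was lost with a pseudocount of 1 (adjusted p = 0.172, 4.52e-05 to 0.172 over the alternatives). Hmces (-2.97), Mras (-2.87), Gsta3 (-2.81) and Id3 (-2.77) completed the 12 largest falls. The call of Id3, an inhibitor of helix-loop-helix factors, was lost without uninduced replicate 1 (adjusted p = 0.0757) and without uninduced replicate 3 (adjusted p = 0.0524), and ranged from 0.00622 to 0.0757 over the alternatives.

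In the proneural cascade 18 of 33 tested members rose at 24 h and 0 fell, with 24 past adjusted over the list alone (camera, adjusted p = 2.6e-14, adjusted p = 0.0955 with an estimated correlation, 2.52e-16 to 0.31 over the alternatives). Neurod4 rose by 3.23 ± 0.39 and Neurod1 by 3.15 ± 0.45. Of the Notch pathway 11 of 30 members rose and 0 fell, with 16 adjusted over the list alone (camera, adjusted p = 3.84e-06, adjusted p = 0.202 with an estimated correlation, 4.97e-08 to 0.418 over the alternatives). Its ligand Dll1 rose by 3.72 ± 0.32 and its target Hes5 by 2.35 ± 0.41. Neural progenitor genes rose in 12 of 28 and fell in 0, with 17 adjusted over the list alone, led by Zic1 at 3.94 ± 0.45 (camera, adjusted p = 1.15e-05, adjusted p = 0.115 with an estimated correlation, 4.04e-07 to 0.336 over the alternatives). Of 48 pan-neuronal genes 15 rose and 5 fell, with 24 adjusted over the list alone (camera, adjusted p = 0.00036, adjusted p = 0.475 with an estimated correlation, 1.12e-05 to 0.574 over the alternatives). Tagln3 rose by 2.11 ± 0.27, whereas Mapt, which encodes the microtubule protein tau, fell by 2.20 ± 0.29. The neuronal tubulin gene Tubb3 was at 1.4 ± 0.39 (adjusted p = 0.0401), a call lost on leaving out any array but induced 24 h replicates 1 and 3 (highest adjusted p = 0.127, without uninduced replicate 3) and ranging from 0.00586 to 0.221 over the alternatives.

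Naive pluripotency genes fell in 17 of 38 and rose in 0 at 24 h, with 20 adjusted over the list alone (camera, adjusted p = 6.82e-15, adjusted p = 0.102 with an estimated correlation, 7.16e-17 to 0.31 over the alternatives). Nanog fell by 2.22 ± 0.38, whereas Pou5f1, which encodes Oct4, was at -0.33 ± 0.45 (adjusted p = 0.684) and Sox2 at -0.35 ± 0.16 (adjusted p = 0.197). The log2 value of Pou5f1 was 12.71 on induced 24 h replicate 1, the array that stood apart, above the uninduced arrays (12.27 to 12.57). On induced 24 h replicates 2 and 3 it was below all uninduced arrays, at 11.94 and 11.69. Nanog no longer passed with the 4 arrays numbered 3 left out, an alternative chosen after seeing the data (adjusted p = 0.0607, 0.000843 to 0.0607 over the alternatives). Primed and formative genes rose in 10 of 18, with 11 past adjusted over the list alone, among them Pou3f1 (3.15 ± 0.55) and Sox3 (2.96 ± 0.55). That list's call (camera, adjusted p = 0.00347, adjusted p = 0.488 with an estimated correlation, 0.000291 to 0.682 over the alternatives) was lost without induced 24 h replicate 1 (adjusted p = 0.068). Genes of cholesterol synthesis rose in 13 of 20 and fell in 0, with 16 adjusted over the list alone (camera, adjusted p = 2.25e-09, adjusted p = 0.135 with an estimated correlation, 3.22e-12 to 0.336 over the alternatives). Tm7sf2 rose by 2.15 ± 0.25 and Fdps by 1.83 ± 0.24. Of 20 cell cycle exit genes 8 rose and 1 fell, with 15 adjusted over the list alone, led by Gadd45g (3.11 ± 0.27) and the CDK inhibitor gene Cdkn1c (2.69 ± 0.36). That list passed (camera, adjusted p = 0.000406, adjusted p = 0.14 with an estimated correlation, 2.33e-05 to 0.336 over the alternatives).

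The ATF4 stress response, a known cellular response to doxycycline, had 4 of 26 members higher and 0 lower at 24 h, with 8 adjusted over the list alone, led by Atf5 (2.03 ± 0.33). Its call (camera, adjusted p = 0.00904, adjusted p = 0.502 with an estimated correlation, 0.00116 to 0.678 over the alternatives) was lost with array weights (adjusted p = 0.0924) and without induced 24 h replicate 1 (adjusted p = 0.0963). The mean of this list was 0.91 above uninduced cells on that array and 0.41 and 0.38 on the other 24 h arrays. Genes of G2 and M phase averaged -0.99 on induced 24 h replicate 1 and 0.04 and 0.02 on the others. Only Cdc25b of the 33 passed, upwards (2.07 ± 0.31), also when adjusted over the list alone. The list test (camera, adjusted p = 0.0351, adjusted p = 0.488 with an estimated correlation, 0.0133 to 0.882 over the alternatives) was lost without that array (adjusted p = 0.563), without uninduced replicate 2 (adjusted p = 0.0543) and with quantile normalization (adjusted p = 0.138). The filter at percentile 75 (camera, adjusted p = 0.0896) and array weights (0.346) ended it too, and fry did not pass (adjusted p = 0.373). Sensory neuron and placode genes rose in 5 of 24 and fell in 0, with 5 adjusted over the list alone, among them Gfra1 (3.20 ± 0.28). That call (camera, adjusted p = 0.0441, adjusted p = 0.279 with an estimated correlation, 0.00124 to 0.524 over the alternatives) was lost without induced 24 h replicate 1 (adjusted p = 0.154), induced 24 h replicate 2 (adjusted p = 0.0646) or uninduced replicate 2 (adjusted p = 0.062). A pseudocount of 1 (camera, adjusted p = 0.0505) or 64 (0.0973), no filter (0.119) and array weights (0.0875) also ended it. Immediate early and heat shock genes, which can mark handling stress, fell in 4 of 26 and rose in 0, whereas adjusted over the list alone 6 fell and 2 rose. Without induced 24 h replicate 1, 8 fell and 1 rose. The list passed (camera, adjusted p = 0.00576, adjusted p = 0.165 with an estimated correlation, 0.000814 to 0.349 over the alternatives).

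In all, 1279 of 12629 genes were called at 24 h, 930 higher and 349 lower, and 1015 of them differed by 1 or more on the log2 scale. The count was 668 without uninduced replicate 1, 768 without uninduced replicate 3 and 2900 without induced 24 h replicate 1. Of the 1279 genes, 1235 were called in the same direction without induced 24 h replicate 1.

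By 48 h 40 of 48 tested pan-neuronal genes were higher than in uninduced cells, and the core pluripotency factor Pou5f1 had fallen (n = 3 against 3). The largest rises included the Notch target Hes5 (6.47 ± 0.41), which was at the floor in uninduced cells (4.12 to 4.19), and the protocadherin gene Pcdh8 (6.35 ± 0.39), Ebf2 (5.96 ± 0.46) and Rgs4, a regulator of G protein signalling (5.90 ± 0.49). The helix-loop-helix factors Nhlh1 and Neurod4 rose by 5.80 ± 0.35 and 5.50 ± 0.39. Ppp1r17 (5.73), Pkdcc (5.62), Rufy3 (5.61), the natriuretic peptide receptor gene Npr2 (5.57), Tox3 (5.53) and Crabp1, which encodes a retinoic acid binding protein (5.47), were the others of the 12 largest rises. Among the 12 largest falls were the ES cell transcription factors Nr0b1 (-5.51 ± 0.32), Pou5f1 (-4.43 ± 0.45), Esrrb (-4.31 ± 0.31) and Klf2 (-4.28 ± 0.53), with Tdgf1 (-5.85 ± 0.71) and Lgals3 (-5.29 ± 0.32). Eras, an ES cell Ras gene (-4.58), L1td1 (-4.44), Morc1 (-4.38), Khdc3 (-4.32), Ooep (-4.25) and Mylpf (-4.23) were the others.

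Pan-neuronal genes rose in 40 of 48 and fell in 3 at 48 h, with 43 adjusted over the list alone (camera, adjusted p = 1.61e-16, adjusted p = 0.114 with an estimated correlation, 6.84e-23 to 0.314 over the alternatives). The granin gene Chgb rose by 5.14 ± 0.34 and Tubb3 by 3.13 ± 0.39, and Mapt was still lower than in uninduced cells (-2.02 ± 0.29). In the proneural cascade 29 of 33 members rose and 0 fell, with 30 adjusted over the list alone (camera, adjusted p = 7.47e-14, adjusted p = 0.0955 with an estimated correlation, 1.38e-16 to 0.31 over the alternatives). Naive pluripotency genes fell in 34 of 38 and rose in 0, with 35 past adjusted over the list alone (camera, adjusted p = 2.11e-20, adjusted p = 0.0905 with an estimated correlation, 9.95e-24 to 0.31 over the alternatives). Of 30 Notch pathway genes 20 rose and 1 fell, with 24 adjusted over the list alone (camera, adjusted p = 9.71e-07, adjusted p = 0.176 with an estimated correlation, 1.24e-08 to 0.349 over the alternatives). Neural progenitor genes rose in 21 of 28 and fell in 2, with 24 adjusted over the list alone (camera, adjusted p = 1.73e-07, adjusted p = 0.0955 with an estimated correlation, 1.08e-09 to 0.31 over the alternatives). Fabp7 of radial glia rose by 4.82 ± 0.65, with log2 values of 9.78, 9.46 and 7.42 on the 48 h replicates 1, 2 and 3. Sox2 fell by 0.71 ± 0.16, a call lost with quantile normalization (adjusted p = 0.133, 0.000143 to 0.133 over the alternatives). Axon guidance genes rose in 25 of 37 and fell in 1, with 28 adjusted over the list alone (camera, adjusted p = 3.85e-07, adjusted p = 0.165 with an estimated correlation, 1.22e-09 to 0.35 over the alternatives). The netrin receptor gene Dcc rose by 4.30 ± 0.33 on the probe set used, and 1 of its 2 further probe sets moved the opposite way.

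At 48 h Cdh2 (N-cadherin) was at 4.43 ± 0.31 and the epithelial gene Epcam at -2.96 ± 0.30. Of 30 epithelial adhesion genes 11 fell and 1 rose, with 13 adjusted over the list alone (camera, adjusted p = 8.95e-05, adjusted p = 0.316 with an estimated correlation, 1.72e-06 to 0.316 over the alternatives). Factors of the epithelial-mesenchymal transition rose in 8 of 13 and fell in 0, with 9 adjusted over the list alone (camera, adjusted p = 0.0179, adjusted p = 0.243 with an estimated correlation, 8.85e-05 to 0.451 over the alternatives). That call was lost with the 4 arrays numbered 3 left out (camera, adjusted p = 0.0578). Neural crest genes rose in 9 of 17 and fell in 2, with 12 adjusted over the list alone, led by Pax3 (4.46 ± 0.29) and Zeb2 (3.59 ± 0.57). Of the 20 genes in the full neural crest list, 14 stand in another list as well. Its call (camera, adjusted p = 0.0327, adjusted p = 0.171 with an estimated correlation, 6.57e-05 to 0.406 over the alternatives) was lost without induced 24 h replicate 1 (adjusted p = 0.0672) and without uninduced replicate 3 (adjusted p = 0.0646). It was also lost with a pseudocount of 1 (camera, adjusted p = 0.0525) or 64 (0.0687), the filter at percentile 75 (0.157) and the mean of all probe sets (0.0509). The fit of the 6 arrays compared alone (0.0648), array weights (0.0641) and leaving out the 4 arrays numbered 3 (0.0652) ended it too. Wnt pathway genes rose in 17 of 34 and fell in 3, with 23 adjusted over the list alone (camera, adjusted p = 0.00885, adjusted p = 0.279 with an estimated correlation, 0.000271 to 0.349 over the alternatives). That call was lost with the filter at percentile 75 (camera, adjusted p = 0.0612). The receptor gene Fzd2 rose by 3.03 ± 0.37, and Fzd5 fell by 2.81 ± 0.24. By 72 h neither this list nor that of the epithelial-mesenchymal transition passed with camera. Of the Wnt genes 12 then rose and 3 fell (camera, adjusted p = 0.0716, 0.000943 with fry). Of the transition factors 7 rose and 3 fell (camera, adjusted p = 0.149, 0.000171 with fry).

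Members of the S phase list fell in 19 of 30 and rose in 0 at 48 h, with 21 adjusted over the list alone (camera, adjusted p = 1.32e-07, adjusted p = 0.125 with an estimated correlation, 7.71e-09 to 0.322 over the alternatives). Those of G2 and M phase fell in 16 of 33 and rose in 0, with 17 adjusted over the list alone (camera, adjusted p = 1.47e-07, adjusted p = 0.114 with an estimated correlation, 1.02e-10 to 0.31 over the alternatives). Without induced 24 h replicate 1, which enters through the shared estimate of the spread, 31 of the 33 fell and 1 rose. The cyclin E gene Ccne1 was at -2.30 ± 0.50 and the mitotic kinase gene Bub1b at -1.59 ± 0.22, whereas Cdkn1c was at 2.94 ± 0.36. Of the ATF4 stress response genes 14 of 26 were lower at 48 h and 2 higher, with 18 past adjusted over the list alone (camera, adjusted p = 0.000107, adjusted p = 0.337 with an estimated correlation, 1.63e-05 to 0.418 over the alternatives). The amino acid transporter gene Slc7a3 was at -3.40 ± 0.39 and Cth at -2.39 ± 0.25. Hox genes rose in 7 of 14 and fell in 0, with 7 adjusted over the list alone, among them Hoxb2 (4.37 ± 0.63) and Hoxb4 (2.94 ± 0.75). The mean of the Hox list above uninduced cells was 1.18, 1.08 and 2.23 on the 48 h replicates 1, 2 and 3. On these arrays the log2 values were 8.31, 8.16 and 9.54 for Hoxb2 and 6.45, 6.46 and 8.68 for Hoxb4. The Hox call (camera, adjusted p = 0.027, adjusted p = 0.542 with an estimated correlation, 0.00532 to 0.69 over the alternatives) was lost without induced 48 h replicate 3 (adjusted p = 0.0796), induced 24 h replicate 1 (adjusted p = 0.0967) or uninduced replicate 2 (adjusted p = 0.0579). A pseudocount of 64 (camera, adjusted p = 0.0926), the filter at percentile 75 (0.156) and array weights (0.0888) also ended it.

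At 48 h 4306 genes were called, 2668 higher and 1638 lower, and 3062 differed by 1 or more on the log2 scale. The split was 2150 higher and 1911 lower with quantile normalization and 2145 and 1896 with median centring. Without induced 24 h replicate 1, which enters through the shared estimate of the spread, the count was 6750, with all 4306 called in the same direction.

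At 72 h 42 of 48 tested pan-neuronal genes and 21 of 28 synapse genes were higher than in uninduced cells (n = 3 against 3). Rufy3 rose by 6.86 ± 0.43, the neurofilament gene Nefm by 6.59 ± 0.43, the LIM homeodomain factor Isl1 by 6.58 ± 0.31 and doublecortin (Dcx) by 6.22 ± 0.31. The synaptic vesicle fusion gene Snap25 rose by 6.09 ± 0.32 and the neuropeptide gene Sst, somatostatin, by 6.27 ± 0.50. Others of the 12 largest rises were Ebf3 (6.33), Ppp1r17 (6.32), Nhlh2 (6.20), Fabp7 (5.99), Onecut2 (5.95) and Nhlh1 (5.93). Tdgf1 (-5.64 ± 0.71), Eras (-5.25 ± 0.43), Nr0b1 (-5.19 ± 0.32), Pou5f1 (-4.80 ± 0.45) and Nanog (-4.58 ± 0.38) were among the 12 largest falls. The others were Lgals3 (-4.87), Morc1 (-4.81), Klf2 (-4.64), Mymx (-4.63), Ooep (-4.53), S100a6 (-4.45) and L1td1 (-4.37).

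The pan-neuronal list had 42 of 48 members higher and 2 lower at 72 h, with 44 past adjusted over the list alone (camera, adjusted p = 3.67e-21, adjusted p = 0.0955 with an estimated correlation, 1.2e-28 to 0.31 over the alternatives). Sensory neuron and placode genes rose in 19 of 24 and fell in 0, with 19 adjusted over the list alone, led by Isl1 and the GDNF co-receptor gene Ret (5.83 ± 0.35). That list passed (camera, adjusted p = 9.93e-09, adjusted p = 0.0625 with an estimated correlation, 7.06e-10 to 0.287 over the alternatives). Synapse genes rose in 21 of 28 and fell in 0, with 21 adjusted over the list alone, among them the vesicular monoamine transporter gene Slc18a2 at 4.43 ± 0.42 (camera, adjusted p = 3.45e-08, adjusted p = 0.115 with an estimated correlation, 2.28e-09 to 0.314 over the alternatives). Epithelial adhesion genes fell in 16 of 30 and rose in 0, with 16 adjusted over the list alone, among them Epcam (-3.82 ± 0.30) and E-cadherin, Cdh1 (-3.03 ± 0.27). Their list passed (camera, adjusted p = 9.99e-06, adjusted p = 0.262 with an estimated correlation, 8.49e-08 to 0.31 over the alternatives). Hypoxia and glycolysis genes fell in 12 of 28 and rose in 3, with 15 adjusted over the list alone (camera, adjusted p = 0.00204, adjusted p = 0.475 with an estimated correlation, 0.000226 to 0.475 over the alternatives). Hexokinase 2 (Hk2) fell by 2.57 ± 0.21. Of 15 germline and 2-cell-like genes 4 fell and 0 rose, with 3 adjusted over the list alone, led by Dnmt3l, a cofactor of DNA methylation (-3.99 ± 0.49). That list passed (camera, adjusted p = 0.0168, adjusted p = 0.49 with an estimated correlation, 0.00534 to 0.574 over the alternatives), a call lost with the filter at percentile 75 (adjusted p = 0.0654).

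Ribosomal protein genes fell in 21 of 26 and rose in 0 at 72 h, with 24 adjusted over the list alone and a median of -0.67. With quantile normalization the median was -0.11 and the list no longer passed (adjusted p = 0.305, against 2.25e-06 as deposited, 0.456 with an estimated correlation and 7.9e-08 to 0.468 over the alternatives). Hox genes rose in 6 of 14 and fell in 0, with 6 adjusted over the list alone, and Hoxb2 rose by 4.23 ± 0.63. The Hox list passed (camera, adjusted p = 0.00738, adjusted p = 0.49 with an estimated correlation, 0.000514 to 0.629 over the alternatives), a call lost with the filter at percentile 75 (adjusted p = 0.187) and with array weights (adjusted p = 0.0752). The mean of the Hox list above uninduced cells was 1.33, 1.18 and 3.07 on the 72 h replicates 1, 2 and 3. Of the lists marking other cells, glia had 5 of 13 genes higher and 4 lower, and endoderm 10 of 21 higher and 4 lower. Neither passed as a list (camera, adjusted p = 0.964 and 0.398, with 0.441 to 0.996 and 0.146 to 0.952 over the alternatives), and adjusted over the list alone 10 and 14 genes passed. The glutamate transporter gene Slc1a2 rose by 4.53 ± 0.42, whereas Apoe, in both lists, fell by 3.21 ± 0.36. The endoderm list averaged 0.34, 0.14 and 1.1 on replicates 1, 2 and 3. Mesoderm and muscle genes rose in 8 of 19 and fell in 2 (10 adjusted over the list alone, camera, adjusted p = 0.369, 0.00201 to 0.754 over the alternatives). The lowest of these was from fry, which tests whether the members move one way and does not compare them with other genes, and was upwards. The largest of these rises were Isl1 and Pax3 (3.73 ± 0.29), which are also transcription factors of sensory neurons and of the neural tube. The mesoderm and muscle median of 0.01 became -0.23 with quantile normalization and -0.18 with median centring. Mesendoderm genes rose in 3 of 8 and fell in 1 (4 adjusted over the list alone, camera, adjusted p = 0.77, 0.0928 to 0.994 over the alternatives), with Foxa2 at 2.19 ± 0.34 and Nodal at -3.73 ± 0.37. For trophoblast 1 of 12 genes rose and 4 fell (5 adjusted over the list alone, camera, adjusted p = 0.162, 0.0405 to 0.574 over the alternatives), and fry passed downwards at the lowest of these. Fibroblast and feeder genes rose in 6 of 21 and fell in 3 (9 adjusted over the list alone, camera, adjusted p = 0.797, 0.373 to 0.942 over the alternatives), with S100a6 among the falls.

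Signalling lists with members moving both ways did not pass at 72 h. BMP and Id genes rose in 7 of 24 and fell in 7 (15 adjusted over the list alone, camera, adjusted p = 0.877, 0.496 to 0.996 over the alternatives), with Id4 at 3.81 ± 0.40 and Inhbb at -4.28 ± 0.28. That list had a median of 0.48 and a mean of 0.09 while the direction of its test was downwards. FGF and MAPK genes rose in 6 of 26 and fell in 7 (13 adjusted over the list alone, camera, adjusted p = 0.225, 0.167 to 0.69 over the alternatives), with Dusp4 at 3.48 ± 0.26 and Fgf4 at -4.37 ± 0.59. For p53 targets 2 of 24 genes rose and 4 fell (3 adjusted over the list alone, camera, adjusted p = 0.614, 0.198 to 0.945 over the alternatives), and Cdkn1a was at 0.88 ± 0.35 (adjusted p = 0.0631). Without induced 24 h replicate 1, 6 p53 targets rose and 5 fell.

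**Figure D3:**
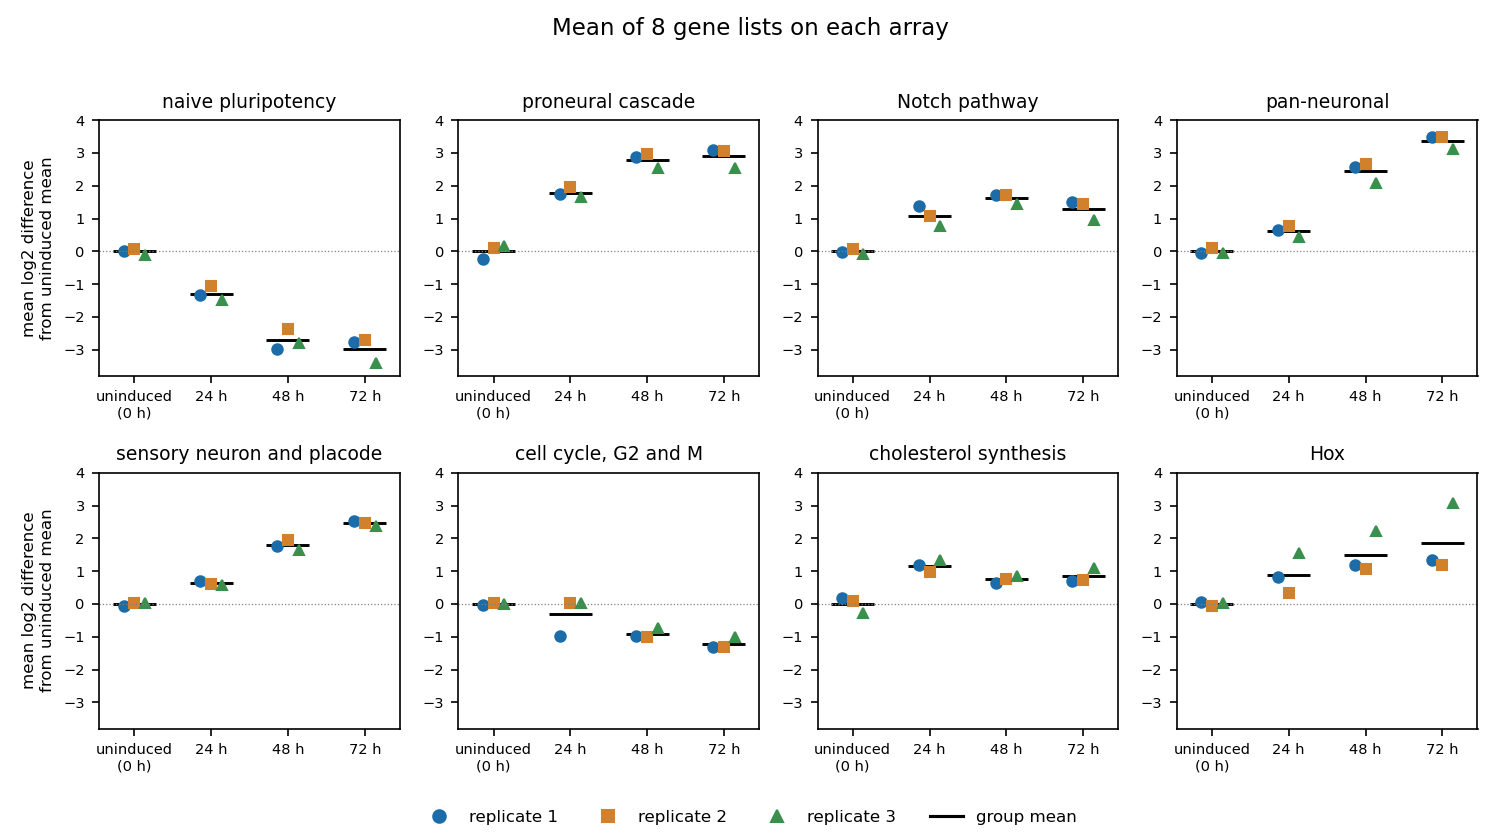
Mean log2 difference from the uninduced group mean of 8 gene lists on each of the 12 arrays against time in doxycycline, with points for arrays by replicate number and bars for group means. The pan-neuronal mean was 0.44 to 0.76 at 24 h and 3.12 to 3.5 at 72 h, the mean of G2 and M phase genes was -0.99 on induced 24 h replicate 1 alone at that time, and the Hox mean was highest on replicate 3 at each induced time.

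In all, 5213 genes were called at 72 h, 3003 higher and 2210 lower, and 3830 differed by 1 or more on the log2 scale. With each array centred on its median the split was 2409 higher and 2729 lower, and centring moved the median difference of all genes from 0.077 to -0.114 at 72 h, from 0.101 to -0.041 at 48 h and from 0.015 to -0.132 for 48 h against 24 h. The camera tests compare a list with the other genes and so are relative to that shift.

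The genes called at the 3 times overlapped. Against uninduced cells 653 genes were higher and 297 lower at all 3 times, of 5818 called at any. Between 48 and 72 h 2359 genes were called higher and 1523 lower at both, where independent lists would share 634.4 and 286.6. For 24 and 48 h the shared calls were 725 and 310, against 196.5 and 45.3, and for 24 and 72 h they were 675 and 310, against 221.1 and 61.1. The values for independent lists leave out the shared controls. The covariance of log2 differences across genes was 1.232 for 48 and 72 h (r = 0.947), against 0.057 (r = 0.501) in simulated unchanged groups with the same 3 controls and no effect of the replicate number. It was 0.495 (r = 0.659) for 24 and 48 h and 0.494 (r = 0.579) for 24 and 72 h, against 0.057 (r = 0.5) simulated for each. The 3 controls cannot be split into sets of 2 arrays, so part of the excess of shared calls over independent lists may come from the shared controls. The simulated covariance already holds the shared controls, and the observed one exceeded it by 1.175 (48 and 72 h), 0.438 (24 and 48 h) and 0.437 (24 and 72 h). In the simulated draws the highest number of genes called the same way at both times was 0. Unchanged groups give almost no calls, so this count cannot measure how far shared controls raise the overlap of the real calls. The draws treated genes as independent. The 950 genes called the same way at all 3 times became 488 without uninduced replicate 1, 563 without uninduced replicate 3 and 2330 without induced 24 h replicate 1.

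Between 24 and 48 h of induction Pou5f1 made the largest fall of any named gene (-4.09 ± 0.45), and 21 of 37 tested axon guidance genes rose (n = 3 against 3). Rufy3 rose by 5.70 ± 0.43, Rgs4 by 5.57 ± 0.49, Ppp1r17 by 4.88 ± 0.30, Dcc by 4.36 ± 0.33 and the growth factor gene Ptn by 4.23 ± 0.36. After Pou5f1, the largest falls were Slc7a7 (-3.90 ± 0.40), Utf1, a chromatin factor of ES cells (-3.8 ± 0.55), Doc2a (-3.76 ± 0.31) and Epas1, which encodes HIF-2alpha (-3.59 ± 0.34). Hes5 rose by a further 4.12 ± 0.41 and Neurod4 by 2.27 ± 0.39, whereas Dll1 was at -0.68 ± 0.32 (adjusted p = 0.163). Id3 rose by 4.06 ± 0.64. Doc2a, among the largest rises at 24 h, was 1 of 136 genes higher at 24 h than in uninduced cells and then lower at 48 h than at 24 h. The opposite course was seen for 18 genes, and the counts were 230 and 43 without induced 24 h replicate 1.

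Pan-neuronal genes rose in 37 of 48 and fell in 0 between 24 and 48 h, with 38 adjusted over the list alone (camera, adjusted p = 1.29e-21, adjusted p = 0.0955 with an estimated correlation, 1.2e-28 to 0.31 over the alternatives). Axon guidance genes rose in 21 of 37 and fell in 0, with 23 past adjusted over the list alone, among them Reln, which encodes reelin (3.18 ± 0.37). Their list passed (camera, adjusted p = 3.64e-10, adjusted p = 0.115 with an estimated correlation, 5.31e-13 to 0.31 over the alternatives). ATF4 stress response genes fell in 18 of 26 and rose in 0, with 18 adjusted over the list alone, led by Nupr1 (-3.25 ± 0.31). That list passed (camera, adjusted p = 2.18e-11, adjusted p = 0.125 with an estimated correlation, 2.1e-13 to 0.31 over the alternatives). Genes of G2 and M phase fell in 17 of 33 and rose in 0, with 17 adjusted over the list alone, among them Pttg1 (-1.56 ± 0.24). The list passed with the preset correlation (camera, adjusted p = 3.45e-06, adjusted p = 0.135 with an estimated correlation, 1.44e-16 to 0.31 over the alternatives). Its mean on induced 24 h replicate 1 was -0.99, within the range of -1.01 to -0.74 at 48 h. Without that array 32 of the 33 genes fell and 0 rose. Cholesterol synthesis genes, higher at 24 h, fell in 5 of 20 and rose in 1, with 6 adjusted over the list alone, among them Fdft1 (-1.26 ± 0.25). That call (camera, adjusted p = 0.0111, adjusted p = 0.49 with an estimated correlation, 0.00491 to 0.638 over the alternatives) was lost without induced 24 h replicate 3 (adjusted p = 0.0991) and with quantile normalization (adjusted p = 0.0572). It did not pass with fry (adjusted p = 0.0586). Against uninduced cells the list still passed upwards at 48 h (10 rose, 1 fell, camera, adjusted p = 0.0126) and 72 h (9 rose, 1 fell, adjusted p = 0.0101). With an estimated correlation both were at 0.49, and without the 4 arrays numbered 3 they were at 0.104 and 0.124. Without induced 72 h replicate 3 the list at 72 h was at 0.051 (camera, adjusted p).

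For 48 h against 24 h 2050 genes were called, 1183 higher and 867 lower, and 1598 differed by 1 or more on the log2 scale. The split was 980 higher and 1160 lower with quantile normalization and 918 and 1082 with median centring. Leaving out induced 48 h replicate 1 gave 1129 calls and leaving out induced 48 h replicate 2 gave 1286. Without induced 24 h replicate 1 there were 2925, of which 1891 were among the 2050 and in the same direction.

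Between 48 and 72 h 86 genes were called, and 10 of 48 tested pan-neuronal genes rose (n = 3 against 3). Sncg, gamma-synuclein, rose by 2.60 ± 0.26 (adjusted p = 0.00116), Mapt by 2.57 ± 0.29, the adhesion gene L1cam by 2.55 ± 0.25 and Ppp1r1c by 2.64 ± 0.30. These calls held when any 1 array was left out but were lost with the 4 arrays numbered 3 left out, at the upper end of 3.82e-07 to 0.0856 over the alternatives for Sncg, 3.27e-07 to 0.0856 for Mapt, 2.6e-07 to 0.0856 for L1cam and 2.06e-06 to 0.117 for Ppp1r1c. Nefm was at 2.73 ± 0.43 (adjusted p = 0.00969), a call lost without induced 72 h replicate 1 (adjusted p = 0.059) and at 0.05 without induced 48 h replicate 3, with 2.11e-05 to 0.259 over the alternatives. Of the 5 largest falls, Myh7b (-2.07 ± 0.31) and Cryba1 (-1.79 ± 0.25) stayed past the threshold when any 1 array was left out, with 1.06e-06 to 0.163 and 2.06e-06 to 0.342 over all alternatives. Gal, Pcolce and Ms4a4d were at -2.14 ± 0.38, -1.96 ± 0.32 and -1.89 ± 0.33, and their calls were lost without induced 48 h replicate 3 (adjusted p = 0.145, 0.0883 and 0.135). Leaving out induced 72 h replicate 1 (adjusted p = 0.14, 0.0665 and 0.0532) or replicate 2 (adjusted p = 0.128, 0.0705 and 0.103) also ended these calls. So did leaving out induced 48 h replicate 1 for Gal (adjusted p = 0.0839), and induced 48 h replicate 2 (adjusted p = 0.0783) or induced 72 h replicate 3 (adjusted p = 0.0806) for Ms4a4d. Over the alternatives their adjusted p ran from 1.06e-06 to 0.266 for Gal, 5.69e-07 to 0.344 for Pcolce and 2.9e-05 to 0.41 for Ms4a4d.

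Pan-neuronal genes rose in 10 of 48 and fell in 0 between 48 and 72 h, with 21 adjusted over the list alone (camera, adjusted p = 9.96e-28, adjusted p = 0.0905 with an estimated correlation, 8.32e-32 to 0.31 over the alternatives). Sensory neuron and placode genes passed with both correlations (camera, adjusted p = 1.42e-11, adjusted p = 0.0448 with an estimated correlation, 4.45e-13 to 0.276 over the alternatives, the highest with that correlation and without induced 24 h replicate 1). Of its 24 members Isl2 rose (1.78 ± 0.20, adjusted p from 1.06e-06 to 0.105 over the alternatives) and 0 fell, and 10 rose adjusted over the list alone. In the synapse list 2 of 28 rose and 0 fell, with 7 adjusted over the list alone (camera, adjusted p = 4.52e-09, adjusted p = 0.114 with an estimated correlation, 7.58e-11 to 0.31 over the alternatives). Without induced 24 h replicate 1, which enters through the shared spread, the rises were 21 pan-neuronal, 8 sensory neuron and placode and 6 synapse genes, with 0 falls. In the Notch pathway list 0 of 30 genes passed with limma, and adjusted over the list alone 1 rose and 2 fell, while the list test passed downwards (camera, adjusted p = 0.000604, adjusted p = 0.34 with an estimated correlation, 3.28e-05 to 0.52 over the alternatives, 0.159 with fry). In the Wnt pathway list, which did not pass (camera, adjusted p = 0.0856, 0.0254 to 0.705 over the alternatives), 1 of 34 genes rose and 1 fell, with 4 adjusted over the list alone. The rise was Rspo2, an enhancer of Wnt signalling (2.48 ± 0.25, adjusted p from 3.82e-07 to 0.138). The neural progenitor factor Dbx1 also rose (1.89 ± 0.23, adjusted p from 1.06e-06 to 0.113).

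For 72 h against 48 h 86 genes were called, 69 higher and 17 lower, each by 1 or more on the log2 scale. The count was 41, 56 and 28 without induced 48 h replicate 1, 2 or 3, 25 and 40 without induced 72 h replicate 1 or 2, and 469 without induced 24 h replicate 1, which kept all 86 in the same direction. With the 4 arrays numbered 3 left out, chosen after seeing the data, limma called 0 genes, against 691 at unadjusted p under 0.05.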

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

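The choice of genes named here, the control ratios and the Neurog1 signal of induced 24 h replicate 1 were tests chosen only after the result was seen. Some genes were called in opposite directions at different times against uninduced cells. Higher at 24 h and lower at 48 h were 10 genes, and higher at 24 h and lower at 72 h were 26. Lower at 24 h were 1 gene that was higher at 48 h and 2 genes that were higher at 72 h. These sets overlap and hold 28 genes, and all 28 also passed limma's test of 48 h against 24 h, which largely restates how they were chosen. The AP-2 factor gene Tfap2c was at 1.08, -1.92 and -2.59 on the log2 scale at 24, 48 and 72 h. Epas1 was at 1.33, -2.26 and -1.95, and Nupr1 at 1.29, -1.96 and -2.34. The neurofilament gene Nefl was at -1.27, 2.24 and 4.76, and Trim2 at -1.95, 0.31 and 2.1.

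Probe sets without a single gene symbol stayed outside the comparisons. Of 3061 tested, 899 passed at 72 h against uninduced cells, 512 higher and 387 lower.

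For each of the 5 comparisons 10 splits of the 6 arrays exist, the real one included, so no share under 0.05 can be had. In each of them 1 split, the real one, gave as many genes past the threshold. The real counts were 1279, 4306, 5213, 2050 and 86, and the highest of the other splits gave 1 gene for 24 h against uninduced and 0 for the other 4 comparisons. Every other split mixes the groups, which adds any difference between them to the spread. Low counts there say nothing further about chance.

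Induced 24 h replicate 1 stood apart from the other 24 h arrays. After quantile normalization its highest correlation with a 24 h replicate was still 0.822, against at least 0.963 in the other groups. Matching the distributions of the arrays thus did not bring it to its group. The authors' scaling could not be tested this way, since a factor per array hardly moves a correlation of log2 values. Centring each array on its median left the lowest correlation within a group at 0.804. A 48 h sample under a 24 h label is argued against, since the median gene lay at 0.04 of the way from the other 24 h arrays to the 48 h arrays, with an upper quartile of 0.75. For an uninduced sample under a 24 h label, the median gene lay at 0.47 of the way from uninduced to the other 24 h arrays (quartiles -0.41 and 1.29), which alone would go with that label, but the Neurog1 signals of 756.3 and 268 lay far above the highest uninduced signals of 18.7 and 7.385 (40.4 and 36.3 times, ratios to signals near the floor and so not exact). Degraded RNA or short cDNA may contribute and stays open, since 1 of 3 control ratios of 3' to 5' signal was above those of all other arrays. No biological explanation was tested, since no group of the design sets this array apart.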

How the results depend on the processing

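Array weights, leaving out the 4 arrays numbered 3, and the estimated correlation without induced 24 h replicate 1 were chosen after seeing the data. Over all alternatives the named genes stayed on their side of the threshold in 10816 comparisons, lost the call in 681, gained it in 18 and reversed in 0. For gene lists these were 4077, 325, 76 and 2. A change of direction counted as a reversal only where the test passed as reported or in the alternative. Changes of direction in tests that passed in neither are within the 10816 and 4077. The 2 reversals were of the direction of the list test, which is relative to the other genes. For ribosomal proteins, 48 h against 24 h with quantile normalization, the median kept its sign at -0.03, against -0.33 as reported (camera, adjusted p = 0.923, range 0.000361 to 0.923). For endoderm, 72 h against 48 h without induced 72 h replicate 3, the median was -0.29, against 0.18 as reported (camera, adjusted p = 0.0305). The range of the endoderm median without 1 array was -0.29 to 0.38. For 72 h against 48 h a pseudocount of 1 gave 19 genes, a pseudocount of 64 gave 229 and the stricter filter 50, and the cause was not tested. The lowest correlation of 2 arrays of a group across genes was 0.804 as reported, 0.878 with no filter and 0.687 with the stricter filter, which tested more and fewer genes. With only the 6 arrays of a comparison, the counts were 337 at 24 h, 6475 at 48 h, 981 for 48 h against 24 h and 421 for 72 h against 48 h, with an overlap of 284. Array weights gave 2231, 6939, 8174, 3246 and 2381 genes for the 5 comparisons and an overlap of 1860. Without the arrays numbered 3 the counts were 423 (24 h), 2667 (48 h), 1229 (48 h against 24 h) and 0 (72 h against 48 h, limma, 691 at unadjusted p under 0.05), with an overlap of 307. Lists past the threshold fell from 89 to 1 with the estimated correlation and to 0 (camera) without induced 24 h replicate 1 as well. Leaving out 1 array gave 668 to 2900 genes at 24 h, 3173 to 6750 at 48 h, 4039 to 7432 at 72 h, 1129 to 2925 for 48 h against 24 h and 25 to 469 for 72 h against 48 h, an overlap of 488 to 2330, a lowest correlation within groups of 0.804 to 0.961 and 82 to 92 lists. The lowest were without uninduced replicate 1 at 24 h and for the overlap, induced 48 h replicate 1 at 48 h and for 48 h against 24 h, and induced 72 h replicate 1 for 72 h against 48 h, and the highest counts of genes were without induced 24 h replicate 1.

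The replicate numbers were not taken to pair the arrays: deviations from the group means of same-numbered arrays correlated across genes over 0.1 in 16 of 18 pairs, from 0.047 to 0.567, and the pairs not over 0.1 were replicate 1 of uninduced and 72 h (0.077) and replicate 2 of 24 and 72 h (0.047). As a hint from the data, not the design, all 12 arrays correlated best on average with arrays of their own number. With the replicate number as a block the counts were 1621, 4712, 5668, 2445 and 91, the overlap 1195 and the lists past the threshold 92. The block ended the list call of EMT factors for 48 h against 24 h (adjusted p = 0.0652, 0.000494 to 0.418 over the alternatives). It gained those of Hox at 24 h (0.0182, 0.00256 to 0.717), for 48 h against 24 h (0.049, 0.0282 to 0.759) and for 72 h against 48 h (0.049, 0.000718 to 0.943), and of immediate early genes for 48 h against 24 h (0.0484, 0.0168 to 0.414).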

Other observations

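The abundant endoderm genes and the quartiles of the retinoid genes were tests chosen only after the result was seen. Replicate 3 arrays at 48 and 72 h had higher Hoxb and retinoid-metabolism genes than the other replicates. At 72 h its log2 excess over the mean of the others was 5.08 for Hoxb6, 4.98 for Hoxb5, 3.8 for the retinoic acid hydroxylase gene Cyp26a1 and 3.65 for the retinoic acid receptor gene Rarb. At 48 h these were 3.37, 2.73, 2.41 and 3.2. Induced 24 h replicate 3 was also above its group, at 8.48 on the log2 scale for Cyp26a1 against 5.36 and 4.64, 8.99 for Rarb against 7.49 and 7.3, and 6.14 for Hoxb5 against 4.29 and 4.13. At 72 h the excess of replicate 3 was -2.62 for Otx2 and -3.32 for Olig2. These genes were chosen after their values were seen.

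The authors' scaling is argued against, since the mean excess of the Hox list at 72 h was 1.98 after quantile normalization and 1.82 as deposited. A retinoid response of the replicate 3 cultures stays open. Of 15 tested genes of a further list of 20, 9 were higher on replicate 3 at 72 h and 10 at 48 h, with quartiles of -0.37 and 0.55 and of -0.32 and 0.64, so the members went both ways. Their median excess of 0.22 and 0.36 was above that of 99.8% and 100% of random lists, which met the bound set before the result was seen and alone would go with a retinoid response. It is left open because of the quartiles, a condition added after those percentiles were seen, and because random lists treat the genes of 1 array as independent. RNA from endoderm-like cells stays open, since 2 of 4 abundant endoderm genes were higher on replicate 3 at 72 h (Lamb1 1.67, Sparc 1.14) while Apoe and Rhox5 were each at -0.47. The whole endoderm list leaned towards replicate 3, with a mean above uninduced cells of 1.1 there and 0.34 and 0.14 on the 72 h replicates 1 and 2. No biological explanation by group was tested, since the replicate number is not a group of the design.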
